A study of Homo sapiens with 2 samples.

How the data were processed

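The material was individual-nucleotide resolution UV crosslinking and immunoprecipitation (iCLIP), an assay that sequences the RNA fragments left bound to a protein after UV light has joined protein and RNA. Per the labels' protocols, H9 cells, an established human embryonic stem cell line that expressed DDX18 with a triple FLAG tag, were grown on inactivated mouse embryonic fibroblasts, irradiated once with 160 mJ/cm2 at 254 nm, and DDX18 was pulled down with an anti-FLAG antibody on magnetic beads. The labels give 2 samples, replicates 1 and 2, in 1 group. Nothing in the labels says whether they came from separate cultures. No input, untagged or other control sample was used here, so no comparison between groups was made.

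The deposited values come as 1 list of significant peaks. Its header shows that the peaks were annotated on the hg19 genome build with annotatePeaks.pl, the annotation program of HOMER, and the submitters' processing notes name FastQC 0.10.1, BWA with no version, and hg19. The peak caller, the treatment of duplicate reads and the rule for significance are not given in the sources used here. Each peak has a height, a signal that the authors deposited as whole numbers with no scaling to depth or RNA abundance. The same number stands in the peak's name beside the gene in which the peak was called, an expected height and a p-value, and these values are the authors' own. The deposited p-value ran from 1e-100, its lower limit, to 0.05. Positions, annotation and the distance to the nearest transcription start site are also the authors'. The list has 1 height per peak and no value per replicate, so the spread between the 2 samples, the reads per sample and the agreement of the replicates were not analysed here. Intervals are exact 95% binomial intervals (Clopper-Pearson) that cover counting error only, since reads and peaks are not independent molecules.

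The list held 17163 entries at 16095 distinct positions, because 1068 entries repeated a position under another gene. Shares of peaks count each position once. Of entries that shared a position, the entry whose RNA class stood first in a fixed order, from rRNA through small RNAs to mRNA, was kept. Gene results use the gene in which the peak was called, and a position called in several genes counts in each. Of the 6695 called genes, 6677 matched the RefSeq gene table by Entrez identifier. That table describes the GRCh38.p14 assembly, not hg19, so it was used for names, biotypes, gene lengths and which genes lie inside each other, and no position was taken from it. Along the promoters whose peaks were called in the gene of the nearest start site and lay at least 50 nt apart, the annotated distance rose in the direction of the gene for 1605 promoters and against it for 0. Peaks were therefore read as called on the gene's own strand. Regions are those of the annotated transcript, which belonged to a gene other than the called one in 808 of 14235 entries in exons and introns of named transcripts (5.68%).

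A peak was assigned to a small RNA class when the nearest start site belonged to a small RNA gene and at least 1 base of the peak lay inside that gene, or when the annotation named a small RNA repeat there. Other peaks took the biotype of the called gene. HOMER places promoter-TSS and TTS (stretches around the starts and ends of transcripts) before exons, introns and repeats. Small RNA genes have start and end sites of their own, so most snoRNA peaks carried those labels. Repeat names were given for intronic and intergenic peaks only, with 0 names in other regions. Peaks of rRNA are therefore those in copies of rRNA sequence within or between genes. Mitochondrial transcripts and the ribosomal DNA arrays were not analysed here.

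The 17 gene lists, the RNA classes, the tests and the rule for naming genes were fixed before the data were examined. The adjustment covers all lists, and 1 of them is not reported here. The H1 part of the histone list was limited to H1-1 to H1-6 when it was coded, and the snoRNA host list holds non-coding genes. The share of list genes with a peak was compared with that of all other protein-coding genes by Fisher's exact test. The mean log2 number of peaks per gene and the median log2 strongest peak height, both over genes with a peak, were compared with the other protein-coding genes with a peak by permutation tests of 100000 resamples, whose smallest possible p is 2e-05. Lists with fewer than 2 such genes were not tested there. Exonic against intronic peaks were compared by Fisher's exact test. All tests were two-sided, and p-values were adjusted over the lists by the Benjamini-Hochberg method with a threshold of 0.05. An adjusted exact p is that of Fisher's test, and an adjusted permutation p that of the resampling. Genes are not independent replicates, so these tests describe this peak list. Tested on 10 simulated tables of 20056 genes, the 3 list tests called 51 of 60 lists simulated at 4-fold odds of a peak, 51 of 60 at a 2-fold number of peaks and 52 of 60 at a 2-fold height. Among unchanged lists they called 2 of 110, 1 of 108 and 1 of 108. The changed lists had 15 to 89 genes, most of them more than the marker lists, and only increases were simulated. The simulated lists shared no genes, and fewer resamples were used. These rates therefore do not describe the smallest lists or lower values. The exon and intron comparison was not simulated.

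Named genes were the 15 with the highest summed height, the 10 with the most peaks, the 3 with the highest summed height in each RNA class, up to 4 per list by strongest peak, and DDX18, NPM1, POU5F1, SOX2 and NANOG. Other names were chosen after their values were seen, and the text says so where they appear. The alternatives fixed beforehand were a stricter p-value, merging of peaks within 50 nt, weighting by height, counting each gene once, exonic peaks only, at least 2 peaks per gene, leaving out small RNAs and repeats, summed in place of strongest height, the median number of peaks, a larger overlap with a small RNA, and a background of genes used in most cells. Counting positions once and taking the called gene were choices made after the file's layout was seen. Exploratory list values had also been seen when 4 alternatives were added, namely the gene of the nearest start site, positions of 1 gene only, matching within 10 groups of gene length, and entries as listed. The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.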

Results

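The RNA bound by DDX18, a DEAD-box RNA helicase of the nucleolus, was measured by iCLIP of FLAG-tagged DDX18 in H9 human embryonic stem cells, to find which RNAs the protein contacts. The group had 2 samples, which share 1 deposited peak list. The list held 16095 distinct peak positions on hg19 with a median width of 13 nt and a median height of 8 (quartiles 6 and 12, range 3 to 76702). Heights summed to 653535. Peaks were called in 6695 genes, among them 6218 of 20056 protein-coding genes (31.0%), and 3639 genes had 1 peak. Because the list carries no value per replicate, no error between samples can be given for any value below, and reads per sample are unknown here.

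Peaks lay mostly in protein-coding transcripts, whereas most of the peak height lay in copies of rRNA. Protein-coding transcripts held 15271 peaks, or 94.9% of positions (95% interval 94.5 to 95.2), with a median height of 8. Sequences of rRNA held 84 peaks, or 0.522% of positions (0.416 to 0.646), but 60.1% of the summed height. The C/D box snoRNAs, which guide RNA methylation, had 157 peaks with a median height of 128, and the H/ACA box snoRNAs, which guide pseudouridylation, had 108 with a median of 81. Together these snoRNAs made up 1.65% of positions and 8.54% of the height. Long non-coding RNAs had 264 peaks (1.64%, interval 1.45 to 1.85) with a median height of 6. Small Cajal body RNAs, spliceosomal snRNAs and tRNAs had 31, 18 and 11 peaks. A further 7 peaks lay in the class of 7SK, signal recognition particle, RNase P/MRP, Y and vault RNAs. Without an input library, heights were not separated from the abundance of each RNA.

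**Figure D1:**
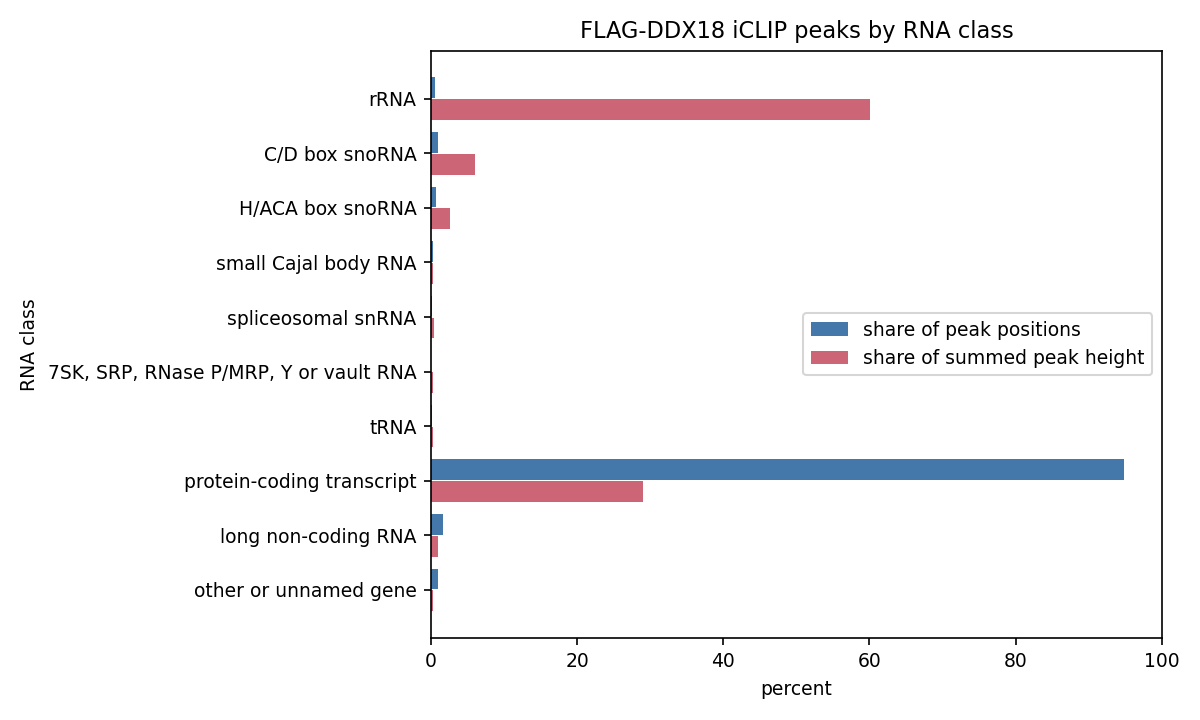
Share in percent of the 16095 peak positions (blue) and of the summed peak height of 653535 (red) in each RNA class, for the pooled list of both FLAG-DDX18 iCLIP samples. Protein-coding transcripts take 94.9% of positions and 29.0% of the height, whereas rRNA copies take 0.522% of positions and 60.1% of the height.

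Of the 84 peaks placed in copies of rRNA sequence, 82 lay in introns. Copies of the small-subunit (18S) type held 17 peaks with a summed height of 241668, copies of the large-subunit (28S) type 43 peaks with 147684, and copies of 5S 24 peaks with 3460. The highest 2 peaks of the list stood in intron 1 of 15 of PDE3A, at positions 20704411 and 20704477 of chromosome 12 on the plus strand, with heights of 76702 and 53870. ANKRD30BL on chromosome 2 had 14 peaks with a summed height of 114125, and 11 of them lay in named rRNA copies. HFM1 on chromosome 1 had a peak of 47395 in intron 4 of 38, SLCO5A1 on chromosome 8 one of 26033 in intron 5 of 7, and PID1 on chromosome 2 one of 11641 in intron 1 of 2. On chromosome 1, the same rRNA-copy peak of height 5301, at positions 145277474 to 145277480, was listed under NBPF10, NBPF9 and NOTCH2NLA. The 10 highest rRNA peaks held 50.5% of all peak height.

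Peaks were found in 142 of the 362 C/D box snoRNA genes of the gene table, in 79 of 182 H/ACA box genes and in 20 of 29 small Cajal body RNA genes. These counts leave out snoRNA genes whose peaks carried a repeat name, such as the U14 copies in HSPA8 and RPS13 and the U17 copies in RCC1. Among the peaks counted as C/D box, SNORD97, inside EIF4G2 on chromosome 11, had the highest, of height 3169. By summed height, the U14 copies in the introns of HSPA8 (4 peaks, 2853) and SNORD28 in SNHG1 (1 peak, 2710) came next. SNHG1 had 8 peaks with a summed height of 6588, all of them in small RNAs. Among H/ACA box RNAs, the U17 copies shared by RCC1 and SNHG3 had 3 peaks with a summed height of 3450, SNORA81 in EIF4A2 had 1058 and SNORA63, also in EIF4A2, had 812. SCARNA2 (424), SCARNA9 (214) and SCARNA10 (194) led the small Cajal body RNAs by summed height. RMRP, the RNA of the nuclease that acts in rRNA processing, had 1 peak of height 1830, and the other leading members of its class were a 7SL copy in TRAPPC12 (9) and a Y3 RNA copy in BLOC1S6 (6). The U2 snRNA copies at WDR74 and in RUBCNL had peaks of 894 and 639, and RNU12 one of 468. The leading tRNA copies lay in an intron of KCTD2 (421) and in intergenic sequence, with peaks called under ARMH4 (358) and ERCC1 (342). TMEM107 on chromosome 17 had 1 peak of height 3529 in its 3' UTR, and the gene table places the C/D box gene SNORD118 (U8) inside TMEM107, although this peak was counted as mRNA. VAV2 on chromosome 9 had a peak of height 3427 in intron 1 of 26, with no small RNA gene inside it.

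Along C/D box snoRNAs the peaks sat toward the 3' end, at a median relative position of 0.665 (0 at the 5' end, 1 at the 3' end), and 124 of 144 peaks (86.1%) lay closer to the 3' end than to the 5' end. Peaks in H/ACA box snoRNAs had a median position of 0.778, with 68 of 105 (64.8%) closer to the 3' end. Peaks in replication-dependent histone genes, whose mRNAs end in a stem-loop in place of a poly(A) tail, lay near the 3' end in all 22 genes that could be placed, at a median of 49 nt from it (quartiles 26.3 and 58). These positions were examined after the peaks had been seen.

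**Figure D2:**
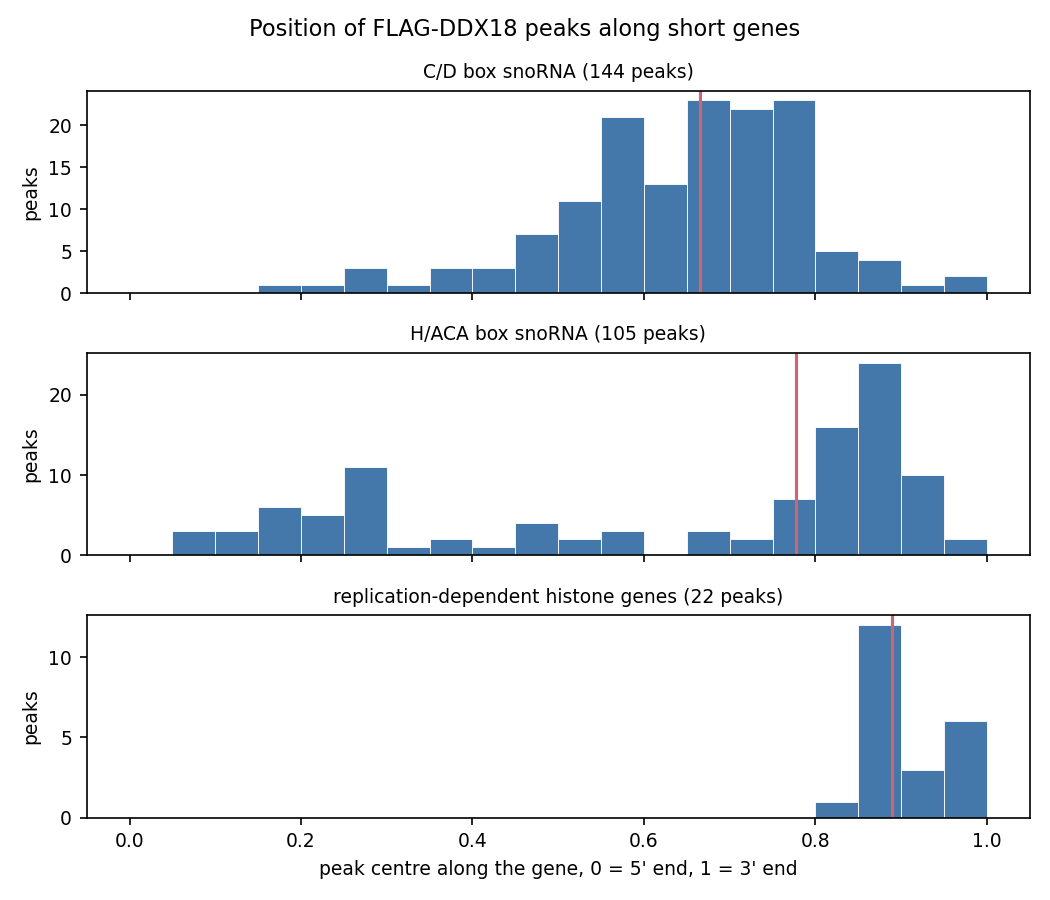
Number of peaks by relative position of the peak centre along the gene (0 at the 5' end, 1 at the 3' end) for 144 C/D box snoRNA peaks, 105 H/ACA box snoRNA peaks and 22 histone gene peaks; red lines mark the medians of 0.665, 0.778 and 0.890. Histone peaks crowd at the 3' end, whereas H/ACA box peaks form a cluster toward each end.

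By transcript region, coding exons held the largest number of peaks, 7512 or 46.7% (45.9 to 47.4). Introns followed with 2965 (18.4%, 17.8 to 19) and 3' UTRs with 2955 (18.4%, 17.8 to 19). Peaks labelled TTS numbered 882 (5.48%) and those labelled promoter-TSS 791 (4.91%). These labels cover stretches around end and start sites, of small RNA genes too, so such peaks need not lie at the site itself. Non-coding exons held 498 (3.09%), 5' UTRs 363 (2.26%) and intergenic sequence 129 (0.801%). Among peaks of protein-coding transcripts alone, coding exons held 48.9% (48.1 to 49.7), 3' UTRs 19.1% and introns 17.6%. Weighted by height, introns held 66.4% and coding exons 12.8%, since 82 of the 84 rRNA-copy peaks were intronic. The shares were not set against the length of each region, because no genome was used here.

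Cytosolic ribosomal protein genes and splicing genes were listed with a peak more often than other protein-coding genes. That background, here and for the lists below, includes unexpressed genes. Expression is not in the peak list, so a higher share was not separated from whether a gene is expressed. A peak was called in 68 of 89 cytosolic ribosomal protein genes (76.4%, 66.2 to 84.8), against 30.8% of the background (odds ratio 7.27, Fisher's exact test, adjusted p = 2.28e-17). RPL17 (881), RPL23A (765), RPL7A (742) and RPL13A (637) had the highest peaks, each of them in a C/D box snoRNA within the gene. Splicing factors and hnRNPs had a peak in 43 of 55 genes (78.2%, odds ratio 8.02, adjusted exact p = 4.12e-12), led by SF3B3 (203, in SNORD111), HNRNPH1 (68), HNRNPA1 (60) and SNRPB (45, in SNORD119). The snoRNA host genes had one in 51 of 63 (81.0%, odds ratio 9.50, adjusted exact p = 3.27e-15). Once peaks in small RNAs and repeats were left out, the odds ratio of ribosomal protein genes was 3.27 and that of snoRNA host genes 1.10 (adjusted exact p = 0.859), which ended the call. With exonic peaks only the odds ratio of snoRNA host genes was 0.471 (adjusted exact p = 0.0953), and with the gene of the nearest start site 0.403 (adjusted exact p = 0.0225). The exonic setting leaves out the 152 of 192 snoRNA host peaks labelled as start or end sites. The snoRNA host list shares 11 genes with the ribosomal protein list.

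Lists of the nucleolus and of ribosome assembly, where DDX18 acts, were also above the background. Of the nucleolar structure and RNA polymerase I genes, 17 of 27 had a peak (63.0%, 42.4 to 80.6, odds ratio 3.79, adjusted exact p = 0.00158). NCL, the nucleolin gene (469), TAF1D, a subunit of a polymerase I factor (413), GNL3 (108) and NOP53 (72) led that list, with the peaks of NCL, TAF1D and NOP53 in snoRNAs. NPM1, which encodes nucleophosmin, had 3 peaks of heights 11, 22 and 17 in its 5' UTR and coding exons 2 and 3 of 10. Ribosome assembly factors had a peak in 34 of 61 genes (55.7%, odds ratio 2.81, adjusted exact p = 0.000204), with the highest at WDR74 (894, in a U2 copy upstream of the gene), WDR43 (375, in SNORD92), NOP58 (230, in SNORD11) and TSR1 (184, in SNORD91B). DEAD-box and DEAH-box helicases had one in 20 of 40 (50%, odds ratio 2.23, adjusted exact p = 0.0288), led by DDX17 (20), DDX3X (15), DHX9 (15) and DDX21 (12). DDX18 itself had 2 peaks, of height 7 at its start site and of height 8 in coding exon 4 of 14. Against genes used in most cells (198 oxidative phosphorylation, mitochondrial ribosomal protein and splicing genes, 50.5% with a peak), none of these 3 lists passed the test: the odds ratios were 1.67 (adjusted exact p = 0.37), 1.23 (adjusted exact p = 0.631) and 0.98 (adjusted exact p = 1). That background was mixed, with a peak in 62.1% of oxidative phosphorylation, 20.8% of mitochondrial ribosomal protein and 78.2% of splicing genes. Odds ratios against it, here and below, depend on that mix. With the gene of the nearest start site the calls of the nucleolar, ribosome assembly and helicase lists ended. Among peaks with a p-value up to the median those of the nucleolar genes and the helicases ended.

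Pluripotency factors had a peak in 16 of 25 genes (64.0%, 42.5 to 82.0, odds ratio 3.96, Fisher's exact test, adjusted p = 0.00164). LIN28A, an RNA-binding protein of stem cells, had 16 peaks with a highest of 36 in its 3' UTR, and L1TD1 had 3 with a highest of 28. DNMT3B, a DNA methyltransferase, had 16 with a highest of 23, and CRIPTO, a Nodal co-receptor, had 5 with a highest of 18. NANOG had 1 peak of height 5 in coding exon 2 of 4, at positions 7945648 to 7945657 of chromosome 12, with a deposited p of 0.0478. No peak was listed for POU5F1 or SOX2. Against genes used in most cells the odds ratio of the list was 1.74 (adjusted exact p = 0.37).

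Genes of chromatin organization and the nuclear lamina had a peak in 27 of 35 (77.1%, odds ratio 7.54, adjusted exact p = 1.06e-07), led by HMGA1 (56), TRIM28 (39), CBX5 (18) and SMARCA4 (17). Polycomb genes had one in 9 of 28 (32.1%, 15.9 to 52.4, odds ratio 1.05, adjusted exact p = 0.894), with JARID2 (21), RBBP4 (14, annotated to the 3' UTR of SYNC), RBBP7 (14) and MTF2 (10) the highest. Nuclear genes of oxidative phosphorylation had one in 41 of 66 (62.1%, odds ratio 3.67, adjusted exact p = 9.54e-07), led by ATP5F1B (94, in SNORD59A), COX7C (48), ATP5F1A (31) and COXFA4 (24). Against the other genes used in most cells this list had an odds ratio of 2.03 (adjusted exact p = 0.0512). Mitochondrial ribosomal protein genes had a peak in 16 of 77 (20.8%, 12.4 to 31.5, odds ratio 0.583, adjusted exact p = 0.0976), with MRPL3 (23, in SNORA58), MRPL12 (10), MRPL22 (8) and MRPL32 (8) the highest. Against the other genes used in most cells their share was lower (odds ratio 0.116, adjusted exact p = 3.23e-10). Histone genes had one in 29 of 69 (42.0%, odds ratio 1.62, adjusted exact p = 0.0867), with an odds ratio of 0.171 (adjusted exact p = 0.000458) for exonic peaks only and of 14 when matched on gene length. The exonic setting leaves out the 35 of 38 histone peaks labelled as start or end sites, so its odds ratio follows from the labels.

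**Figure D3:**
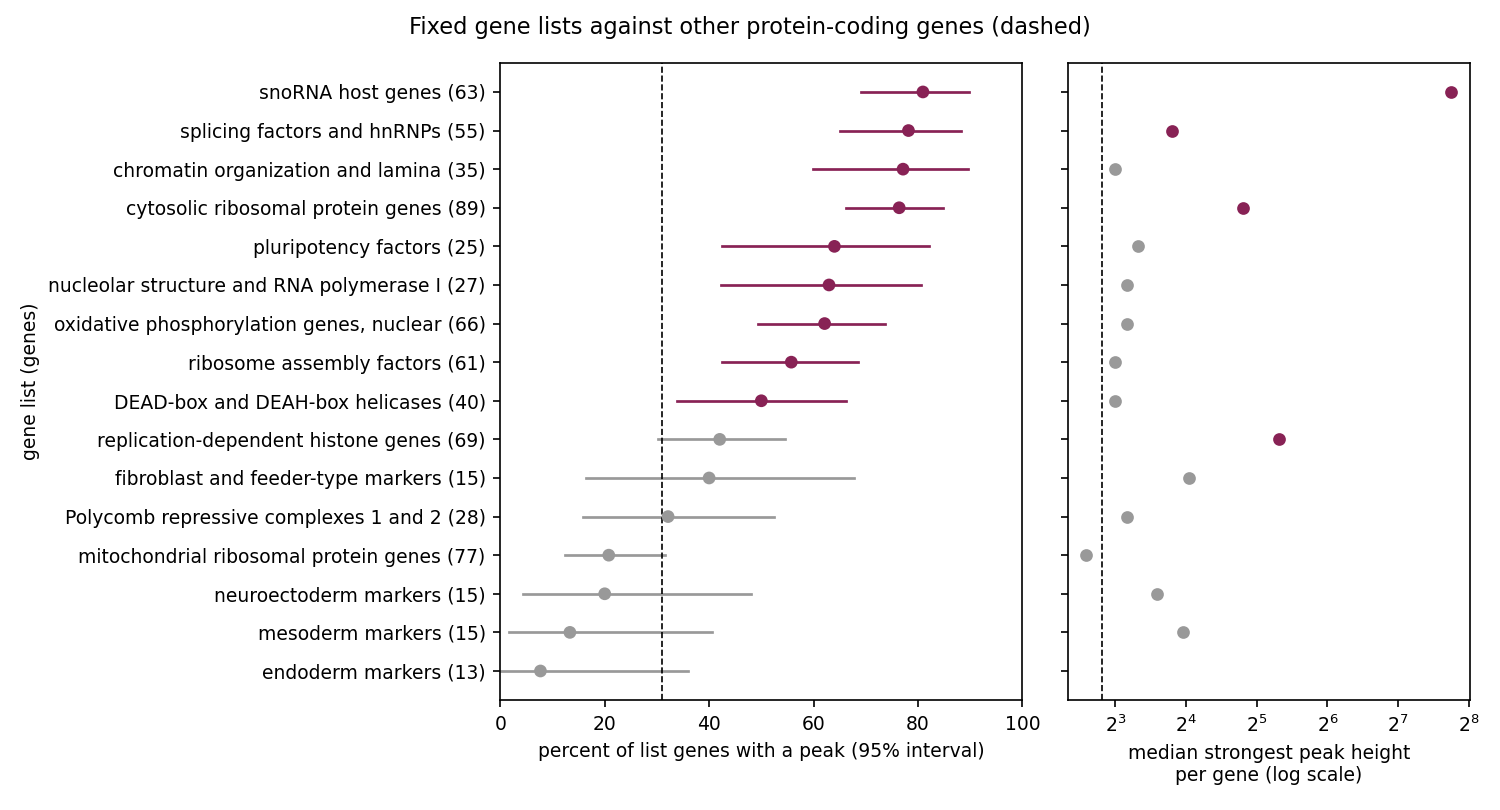
Left, percent of the genes of each reported list with a peak, with exact 95% intervals and the number of list genes in brackets. Right, median height of the strongest peak per gene on a log scale. Dark red marks an adjusted p under 0.05 in the test of that panel, grey the others, and dashed lines mark the other protein-coding genes (31.0% with a peak, median height 7). The snoRNA host genes stand highest in both panels.

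No list of markers of other cell types passed the test of the share of genes with a peak. Neuroectoderm markers had a peak in 3 of 15 genes (odds ratio 0.556, adjusted exact p = 0.654), namely NES (15), TUBB3 (12) and OTX2 (9). Mesoderm markers had one in 2 of 15 (odds ratio 0.342, adjusted exact p = 0.223), KDR (16) and PDGFRA (15), and endoderm markers in 1 of 13 (odds ratio 0.185, adjusted exact p = 0.109), SOX7 (13). The PDGFRA peak of height 15 was annotated to an intron of GSX2, 2 of its 3 peaks were also called in other genes, and the SOX7 peak was intergenic, upstream of SOX7. Fibroblast and feeder-type markers had one in 6 of 15 (40%, odds ratio 1.48, adjusted exact p = 0.509), led by THY1 (39), COL6A1 (26), COL1A1 (17) and COL1A2 (16). The cells were grown on mouse fibroblasts, and reads of that species were not separated here. Against genes used in most cells, the mesoderm and endoderm lists were lower (odds ratios 0.151 and 0.0817, adjusted exact p = 0.0151 and 0.00979).

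Among genes with a peak, 5 lists had more peaks per gene than other protein-coding genes, whose geometric mean was 1.78. Splicing genes averaged 3.04 peaks (difference of mean log2 0.78, SD over genes 1.11, permutation test, adjusted p = 0.00048) and snoRNA host genes 2.99 (0.76, SD 1.04, permutation, adjusted p = 0.00048). Chromatin and lamina genes averaged 2.70 (adjusted p = 0.0193), ribosomal protein genes 2.24 (adjusted p = 0.0307) and the 6 fibroblast markers 5.54 (permutation, adjusted p = 0.0071). Fewer peaks per gene were found in mitochondrial ribosomal protein genes, with 1.07 (difference -0.73, adjusted permutation p = 0.00395), and in histone genes, with 1.22 (difference -0.54, adjusted permutation p = 0.0071). With exonic peaks alone the difference of ribosomal protein genes changed sign, to -0.31 (adjusted permutation p = 0.238). That setting leaves out the 106 of their 171 peaks labelled as start or end sites, so the change may follow from the labels. With small RNAs and repeats left out the difference of ribosomal protein genes was 0.19 (adjusted permutation p = 0.372). The call of snoRNA host genes also ended without small RNAs and repeats, and that of histone genes when matched on gene length. With 2 peaks or more per gene, none of the 5 lists remained higher, and ribosomal protein genes were lower (-0.35, adjusted permutation p = 0.0202). Among peaks with a p-value up to the median only the snoRNA host genes did, and with exonic peaks alone only splicing genes and fibroblast markers. The calls of the mitochondrial ribosomal protein and histone genes ended in both of the latter settings and, like that of cytosolic ribosomal protein genes, with the median number of peaks. The other 9 of 16 tested lists did not pass, including pluripotency factors (2.19 peaks, adjusted permutation p = 0.391) and nucleolar genes (2.22, adjusted permutation p = 0.391).

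The strongest peak per gene was higher in 4 of the 16 lists than the median of 7 in other protein-coding genes, each by a permutation test at the smallest p it can give (2e-05, adjusted p = 8e-05). The median was 216 in snoRNA host genes, a log2 difference of 4.95 (SD over 51 genes 2.15). Their highest peaks were in EIF4G2 (3169), SNHG1 (2710), HSPA8 (1472) and RCC1 (1228), all in snoRNAs. It was 40 in 29 histone genes (difference 2.51, SD 0.76), with H4C12 (106), H3C2 (87), H4C8 (80) and H4C6 (69) the highest. It was 28.0 in 68 ribosomal protein genes (difference 2.0, SD 2.13) and 14 in 43 splicing genes (difference 1.0, SD 1.0). With small RNAs and repeats left out, the differences of snoRNA host and ribosomal protein genes were 2.0 and 1.32 (adjusted permutation p = 8e-05 for both), and that of histone genes was 1.41 against random sets of matched gene length. With exonic peaks alone the call of histone genes ended (difference 0.89, adjusted permutation p = 0.385). That setting leaves out the 35 of 38 histone peaks labelled as start or end sites, so the lost call says little about these genes. Peak strength in the pluripotency list (median 9.95, difference 0.51) did not pass after adjustment (adjusted permutation p = 0.129). Nor did it in nucleolar genes (9, difference 0.36, adjusted permutation p = 0.39) or ribosome assembly factors (8, difference 0.19, adjusted permutation p = 0.608). Of the lists that did not pass, the fibroblast markers came nearest (6 genes, median 16.5, difference 1.24, adjusted permutation p = 0.0516).

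Peaks in exons against introns leaned to exons in 5 of 16 lists. Splicing genes had 141 exonic and 6 intronic peaks (95.9% exonic against 79.1% in other protein-coding genes, odds ratio 6.20, Fisher's exact test, adjusted p = 2.18e-07). Pluripotency factors had 54 and 2 (96.4%, odds ratio 7.07, adjusted exact p = 0.0022), and fibroblast markers 37 and 0 (100%, interval 90.5 to 100, adjusted exact p = 0.0022). Oxidative phosphorylation genes had 51 and 3 (94.4%, adjusted exact p = 0.0146), and ribosomal protein genes 60 and 5 (92.3%, adjusted exact p = 0.0263). The snoRNA host genes had 27 and 12 (69.2%, odds ratio 0.587, adjusted exact p = 0.237). Among peaks with a p-value up to the median, only the splicing genes of these 5 lists passed. With the gene of the nearest start site, the calls of pluripotency factors, oxidative phosphorylation genes and ribosomal protein genes ended. Peaks labelled as start or end sites, which include 106 of the 171 ribosomal protein peaks, did not enter this comparison. The test counts peaks as if independent, although peaks of 1 gene are not. Among pluripotency factors, LIN28A had 3 peaks in coding exons and 12 in its 3' UTR, and DNMT3B 11 and 5. The fibroblast peaks came from 6 genes. These p-values therefore do not measure how many genes of a list lean to exons.

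FRAS1, an extracellular matrix gene on chromosome 4, had the largest number of peaks in the list, 56, with none higher than 22, and DYNC1H1, the dynein heavy chain, had 51. HSPG2, which encodes perlecan, had 44, PRKDC, a DNA repair kinase, had 43, MACF1 had 42, KIF1A 39, LRP1 39 and PTPRZ1 38. SNORD109A and SNORD109B, each 67 nt long, were listed with 43 peaks each on chromosome 15, and all of these positions were also called in other genes. Both had the same summed height (1539) and the same highest peak (113), whose nearest start site was that of SNORD116-21. Their 43 peaks are therefore not read as binding of these 67 nt RNAs. Of the nuclear long non-coding RNAs of the fixed class, MALAT1 had 7 peaks with a highest of 49, MEG3 1 of height 119, TUG1 1 of 10, NEAT1 1 of 8 and KCNQ1OT1 1 of 6. No peak was listed for H19, LINC-ROR, LINC00678, ESRG or TINCR.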

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

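The repeat families and the peak named here, and the comparison with the limit of a count of 0, were chosen after the repeat names had been seen. Interspersed repeats, which the report left out in 1 setting but did not describe, held peaks. With no control sample, the reference is the limit that a count of 0 among 16095 positions allows, 0.0186%, a bound that a family with very few peaks passes. No share to be expected from the repeat content of introns was computed, so the counts show that such peaks are listed and nothing about enrichment. Peaks in L1 repeats numbered 278 (1.73%), in Alu repeats 237 (1.47%), in MIR repeats 105 (0.652%) and in L2 repeats 90 (0.559%), with a median height of 6 in each family. The highest peak in an interspersed repeat, of height 1033, lay in an L1M4 copy in intron 59 of 61 of ABCA13, at positions 48672390 to 48672394 of chromosome 7 on hg19. Repeat names were given for 1197 of 3094 intronic and intergenic peaks (38.7%). Copies of a repeat can share reads, and no explanation of these peaks was tested.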

How the results depend on the processing

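The alternatives with the gene of the nearest start site, without positions of several genes, matched on gene length and with entries as listed were chosen after the data had been seen. No paired analysis was possible because the list holds 1 group and no value per replicate. For the same reason the runs without replicate 1 or replicate 2 and the agreement of the replicates were not run, and without a genome region shares were not set against region lengths. Requiring a larger overlap with a small RNA changed 0 RNA classes, so it says nothing about stability. Merging peaks within 50 nt changed no call of a list. Over all alternatives, 129 list values for the share of genes with a peak kept their side of the threshold, 10 lost the call, 10 gained it and 4 changed direction. A change of direction was counted only where the main or the alternative value was called, and apart from calls lost or gained. Values called in neither setting could therefore change direction and still count among the 129. These counts were 113, 27, 0 and 2 for peaks per gene, 134, 1, 7 and 0 for peak strength, and 55, 7, 2 and 0 for exons against introns. The number of reads is unknown, so what depth limits was not assessed. Where an alternative's construction does not show it, the cause was not tested.

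Among peaks with a p-value up to the median, rRNA held 0.976% of positions, snoRNAs 3.23%, protein-coding transcripts 92.4%, coding exons 47.9%, introns 14.4%, 5' UTRs 2.68%, promoter-TSS 6.59% and TTS 6.21%. Merging gave 94.1% in protein-coding transcripts. Weighting by height gave 60.1% rRNA, 8.54% snoRNA, 29.0% protein-coding and 0.889% long non-coding, with 12.8% in coding exons, 5.90% in 3' UTRs, 66.4% in introns, 0.768% in 5' UTRs, 9.39% in promoter-TSS and 3.35% in TTS. Counting each gene once per class gave 0.808% rRNA, 4.30% snoRNA, 89.7% protein-coding and 2.50% long non-coding, with 33.3% in coding exons, 19.4% in 3' UTRs, 23.6% in introns, 3.43% in 5' UTRs, 7.49% in promoter-TSS and 8.34% in TTS. Entries as listed gave 2.71% snoRNA, 91.7% protein-coding, 2.23% long non-coding, 45.3% in coding exons and 6.30% in promoter-TSS.

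For the share of genes with a peak, 9 lists were higher and 0 lower. The number lower was 1 with the better p-values, 2 with exonic peaks only and 1 with 2 peaks or more. Against genes used in most cells 4 lists were higher and 3 lower, and with the nearest start site 5 were higher and 1 lower. The nucleolar and helicase lists lost the call with the better p-values and, like ribosome assembly factors, with the nearest start site. The odds ratio of snoRNA host genes turned to 0.471 with exonic peaks only, which leaves out their many peaks labelled as start or end sites. It turned to 0.403 with the nearest start site, where snoRNA peaks go to the snoRNA's own gene. The odds ratio of histone genes turned to 0.171 with exonic peaks only, which leaves out peaks at transcript ends. That of DEAD-box and DEAH-box helicases turned to 0.98 against genes used in most cells.

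For peaks per gene, 5 lists were higher and 2 lower. These became 1 and 0 with the better p-values, 2 and 0 with exonic peaks only, and 0 and 1 with 2 peaks or more, where 14 lists were tested. The number higher was 3 without small RNAs and repeats and 3 without positions of several genes. With the nearest start site 2 were higher and 1 lower. The number lower was 1 when matched on gene length and 0 with the median, where ribosomal protein genes also lost the higher call. The difference of ribosomal protein genes turned to -0.31 with exonic peaks only, which leaves out their many peaks labelled as start or end sites. It turned to -0.35 with 2 peaks or more. For peak strength, 4 or 5 lists were higher in every alternative run, but with exonic peaks only histone genes lost the call and fibroblast markers gained it. Of exons against introns, 5 lists were more exonic and 0 less. With the better p-values 1 was more and 1, the snoRNA host genes, less exonic, and with the nearest start site 3 were more exonic, 1 of them (ribosome assembly factors) not among the 5.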

Other observations

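The tests of gene symbol groups, exon rank, rRNA copies, histone peak heights and matched gene length, and the limits of 100 and 10-fold for rRNA copies and of 80 and 1500 nt for histone genes, were chosen after the result was seen. Protein-coding genes were grouped by the letters that open their symbols, for the 148 groups of at least 15 genes. By Fisher's exact test, adjusted over these groups, 18 were listed with a peak more often than other genes and 29 less often. No peak was listed for the 392 olfactory receptor genes (OR, adjusted exact p = 2.52e-62), 94 keratin-associated proteins (KRTAP, adjusted exact p = 6.11e-14) or 39 beta-defensins (DEFB, adjusted exact p = 1.72e-05). Cytochrome P450 genes (CYP) had one in 4 of 56 (7.14%, adjusted exact p = 0.000503) and keratins (KRT) in 3 of 55 (5.45%, adjusted exact p = 0.000126). Nucleoporins and other NUP genes had a peak in 20 of 23 (87.0%, odds ratio 14.9, adjusted exact p = 1.52e-06) and translation initiation factors (EIF) in 34 of 56 (60.7%, odds ratio 3.45, adjusted exact p = 0.000126). SEC genes had one in 19 of 29 (65.5%, adjusted exact p = 0.00128) and semaphorins (SEMA) in 15 of 20 (75%, adjusted exact p = 0.000744). Gene length was not matched here and expression was not analysed.

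On chromosome 15, from position 25207276 to 25357018 of hg19, the stretch from SNRPN to IPW held 81 peaks with a summed height of 2081. Of these, 33 counted as protein-coding transcript (summed height 425), 24 as long non-coding RNA (851) and 18 as C/D box snoRNA (732). Outside small RNAs, peaks of height 1000 or more also stood at TSC2 (1818, start site), LUC7L2 (1753, annotated to the start site of FMC1), CACNA2D3 (1738, intron 3 of 37), MIR663AHG (1459, nearest to the start of MIR663A) and MTFP1 (1269, annotated to the 3' UTR of SEC14L2). ANKRD30BL had 3 such peaks not named as rRNA copies, of heights 2523, 1306 and 1051. Those of 2523 and 1051 carried the start-site label, as did those at TSC2, LUC7L2 and MIR663AHG. Repeats were not named at start sites, so an rRNA copy at these peaks would not have been seen. A tRNA gene lies inside LUC7L2. With the exons of each transcript put in 5 groups by rank, the first group held 21.7% of 7490 coding-exon peaks, the next 19.9% and the last 21.3%, where 23.4%, 18.1% and 21.9% would follow if every exon were alike. This stretch and these peaks were also chosen after their values were seen.

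Copies of rRNA inside introns held most of the peak height. If the unspliced transcript of the host gene were bound along its length, its other sequence should carry peaks of similar height. Of 21 host genes with an rRNA-copy peak of at least 100, genes listed for the same position counted once, 21 (100%) had no other peak or only peaks at least 10-fold lower. Of these 21 host genes, 19 had no other peak at all, so binding along these transcripts at similar height was not seen. However, of 55 genes picked by another peak of at least 100 outside named small RNAs and repeats, 34 also had no other peak. The same bound was met by 40 of these 55 genes (72.7%, Fisher's exact test, p = 0.00767). Both groups were picked by a high peak in a list with few of them, so the test cannot decide the cause. Their peaks were lower (median 158 against 1554), so the bound does not mark out rRNA copies. Binding of the host transcript at the copy alone cannot be told apart here from reads of rRNA aligned to its genomic copies. Nor can the abundance of rRNA, since no input was used.

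Ribosomal protein genes and snoRNA host genes had stronger peaks than other genes. For ribosomal protein genes the log2 difference of 2.0 was 1.32 without small RNAs and repeats (adjusted permutation p = 8e-05) and 1.45 against random sets of matched gene length (adjusted permutation p = 0.000107), which argues against either as the whole source. For snoRNA host genes the difference of 4.95 was 2.0 without small RNAs and repeats, over the 19 of 63 genes that then had a peak and still past the threshold, so small RNAs inside these genes may account for most of it. A difference of 4.50 against sets of matched length argues against gene length as the whole source. Expression of the genes stays open and was not tested.

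Histone gene peaks lay within 80 nt of the 3' end in all 22 genes placed. Among other protein-coding genes under 1500 nt, 1 of 10 peaks (10%) did (Fisher's exact test, p = 3.57e-07), but the window was set on the histone peaks, these 7 genes were longer (median 1206 nt against 495), and 7 of their 10 peaks lay closer to the 3' end than to the 5' end, at a median relative position of 0.821 against 0.890. A 3' preference of the library in short transcripts and one of histone genes cannot be told apart from these peaks. The 22 genes had 19 distinct heights from 25 to 106, which argues against 1 cluster of reads copied to every gene. Reads shared in part between near-identical histone genes stay open, and no biological explanation was tested.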
